A study of Homo sapiens and Mus musculus with 71 samples.

How the data were processed

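The series holds 71 samples, of which 40 RNA-seq libraries were analysed: 28 from human embryonic stem cells of the line WIBR3 and 12 from mouse embryonic stem cells of the line V6.5. They form 20 groups of 2 libraries. The other 31 samples were not analysed here: 4 GRO-seq samples, 12 samples of a neural induction of NANOG-tagged cells and 15 amplicon samples. Groups and replicate numbers were taken from the sample labels. The labels do not say that the replicates of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The RepSox table does not name the assay in its column names and was read as the RNA-seq libraries of that treatment.

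The values came in 6 tables. In 4 of them the authors deposited whole-number counts of reads per gene, not normalized. In the tables of the NANOG, MIR302 and ACTB intron 1 lines and of the Lncenc1 line the authors deposited expected counts, of which 17.3 to 19.3% and 11 to 12.1% per library were not whole within a tolerance of 1e-06; these were rounded before the count tests. Per the submitters' processing notes, FastQC 0.11.9, Trim Galore 0.6.7, STAR 2.7.10a, Bowtie2 2.4.5, Subread and featureCounts 2.0.1 were used with the builds hg38, mm10 and GRCh38; the notes do not say which tool served which table. Whether counting used strand is not given in the sources used here, so reads of overlapping genes on opposite strands were not taken as separable. The whole-number human tables list 68247 genes each, 6395 of them on sequences outside the main chromosomes, and gene symbols were found for 90.5%. The table with the reporter control lists 61544 genes and symbols were found for 99.8%. For the 55401 genes of each mouse table no names were used, since no table pairs their identifiers with names; at most 2 identifiers that rose and 2 that fell are given per comparison, and gene lists were not tested in mouse.

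Total counts per library, in M (1e+06), ran from 79.9 to 114 for the reporter control and the NANOG, MIR302 and ACTB intron 1 lines, from 12.1 to 37.8 for the polyA lines, from 86.6 to 133 for the Lncenc1 line and its control, from 7.88 to 15.3 for the differentiation, from 20.5 to 27.8 for UNC0638 and from 24.1 to 38.7 for RepSox. Within every group the replicates differed by more than sampling noise, with a chi-square per degree of freedom between 1.5 and 235 over genes with a summed count of at least 20. This spread may be technical, and libraries were counted as replicates because the labels number them so.

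The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, the filterByExpr filter on low counts with the groups given, all groups of a table in a shared fit and no replicate block. Genes past a Benjamini-Hochberg adjusted p of 0.05 were called, and every adjusted p for a gene comes from this test. Counts per M (CPM) are scaled by TMM factors of the genes tested in the comparison; those in the figures of human genes and in the closing observations on human genes use factors from all genes of a table, so the same library differs slightly between the scales. A log2 change is the value of the group named before the word against, minus that of the other. Standard errors are those of the fitted log2 change. The ACTB polyA and SOX2 polyA lines stand in another table than the reporter control, so the tables were joined on shared genes; line and table cannot be told apart in these comparisons. A comparison of both polyA lines within their own table was added after the data were examined. Where all libraries of a group stood at 0, the fold is a lower bound against 3 counts over the group. Where a group held 1 to 3 counts, the ratio is given with a 95% counting interval. Bounds and intervals cover counting error only.

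Gene lists for functional groups and cell types were fixed before the data were examined, 22 of them for human genes. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, a rotation test of a list by itself. List counts give members past the gene threshold over all genes tested, and adjusted over the list alone where that differs. Genes were named by a rule fixed before the data were examined: all tagged and target loci; genes within 200 kb of the tagged gene; up to 3 called members with the largest change from each list that passed its test and 1 from each other list; and the 4 largest increases and decreases among called genes with a mean of at least 1 CPM, no overlap between groups and a symbol that is not a clone name. Y-linked genes were left out of the naming. Genes outside the rule are marked where they appear.

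Each comparison was tested on simulated data in which 100 genes were changed 2-fold and 100 others 4-fold. These data used each gene's mean pooled over all groups, the trend of dispersion with level and the real library sizes. Departures of single genes from that trend were left out, so recovery in the real libraries may differ. Of the 2-fold changes, 82 were recovered for Lncenc1, 74 for RepSox, 73 for the polyA lines against each other, 25 for NANOG, 34 for MIR302, 31 for ACTB intron 1, 28 for ACTB polyA, 27 for SOX2 polyA, 20 for day 5, 24 for day 12, 20 for day 20, 21 for day 14, 13 for UNC0638 at 48 h and 11 at 7 days. Of the 4-fold changes, between 64 and 93 were recovered in these comparisons. For the difference between the UNC0638 effects at both times, 0 of the 2-fold and 30 of the 4-fold changes were recovered.

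Alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 test (DESeq2 1.42.0), each replicate left out in turn, the replicate number as a block, and only the compared groups in the fit. Chosen after the data were examined were, for the polyA lines, only genes with whole control values, only genes not empty in all whole-number human tables, and DMSO-treated wild-type cells as the control; and for UNC0638 at 7 days, the 7-day libraries alone with the block. The test of outlying libraries and the count of other splits were set for larger groups and were not run on groups of 2. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.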

Results

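RNA was sequenced from stem cells that carry REDDIT, the study's ribozyme-assisted RNA editing reporter, at the loci NANOG, MIR302, ACTB or SOX2 in human WIBR3 cells and at Lncenc1 in mouse V6.5 cells. It was also sequenced from a differentiation of MIR302-tagged cells towards cardiomyocytes, from mouse cells treated with UNC0638 and from human cells treated with RepSox. Each group held 2 libraries. The labels describe RNA libraries selected for poly(A), human cells grown in mTeSR on Matrigel and mouse cells grown on gelatin with serum and LIF. The human control line carries an mCherry-TAG-GFP reporter. Library totals ran from 7.88 M counts (M, 1e+06) in the differentiation to 133 M in the mouse control.

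The comparisons of tagged lines with their control ask how far the transcriptome of each line departs from that of cells with the reporter alone. In the NANOG line, transcripts of NANOG itself stood at 65.1 ± 3.87 CPM (SD, n = 2) against 146 ± 7.51 CPM in the control, 2.25-fold lower (log2 change -1.17, SE 0.15, adjusted p = 0.0126). NANOG (ENSG00000111704), a homeodomain factor of pluripotent cells, lies on chromosome 12 from 7787794 to 7799146 in hg38 on the plus strand, and its pseudogene copies make its count uncertain. Other genes of undifferentiated cells were also lower: ZFP42 by a log2 change of -4.00, HHLA1 by -4.48 and DPPA2 by -2.20, from 36.5 and 33.2 CPM to 7.03 and 8.13. The growth factor gene FGF4 changed by -3.53. NLRP7, a gene of oocytes and early embryos, was at 0 in both NANOG libraries, at least 80.3-fold lower. The microtubule gene MAP2 rose by 2.51, from 17.8 and 26 CPM to 146 and 104, and the neural transcription factor gene ZIC2 rose by 1.35. SOX2 was at 279 and 314 CPM against 309 and 280 (adjusted p = 0.987).

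By list, 5 of 25 core pluripotency genes fell and none rose in the NANOG line (8 fell when adjusted over the list alone), with camera adjusted p = 1.6e-06 but adjusted p = 0.261 with an estimated correlation. Of 16 naive pluripotency genes 3 fell (1 rose and 8 fell adjusted over the list alone; adjusted p = 1.6e-06, and adjusted p = 0.261 with an estimated correlation). Of 22 neuroectoderm genes 2 rose (6 over the list alone; adjusted p = 0.000595, and adjusted p = 0.266 with an estimated correlation). In the Nodal list, which holds NANOG, NANOG was the 1 member of 21 that fell (1 rose and 6 fell adjusted over the list alone; adjusted p = 0.00329, and adjusted p = 0.266 with an estimated correlation). None of 18 genes of the amino acid and ATF4 response passed over all genes, 8 rose adjusted over the list alone, and the list ranked high (adjusted p = 9.65e-08, and adjusted p = 0.261 with an estimated correlation). Of 19 glycolysis genes 1 fell, PKM, which encodes pyruvate kinase (log2 change -0.75; 4 fell over the list alone; adjusted p = 1.6e-06, and adjusted p = 0.261 with an estimated correlation). None of 16 heat shock and immediate early genes passed over all genes, and 7 fell adjusted over the list alone. That list ranked low (adjusted p = 0.00389, and adjusted p = 0.261 with an estimated correlation). So did 14 primitive streak genes (adjusted p = 0.0471, and adjusted p = 0.266 with an estimated correlation), of which 2 fell over the list alone. The noncoding RNA LINC01108 showed a decrease from 242 and 211 CPM to 5.39 and 3.92, a log2 change of -5.61 (SE 0.262, adjusted p = 0.000158). The zymogen granule gene CUZD1 rose by 4.65 and the secretogranin gene SCG2 by 3.77.

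In all, 358 of 29032 genes passed in the NANOG line, 136 higher and 222 lower, against 1635 (772, 863) with DESeq2 and 2308 (966, 1342) with no filter on low counts. The count was 35 (7 higher, 28 lower) and 33 (7, 26) without NANOG replicate 1 and 2, and 2319 (1246, 1073) and 2662 (1128, 1534) without control replicate 1 and 2; NANOG, ZFP42, HHLA1, ZIC2, PKM and SCG2 lost their calls without either NANOG replicate and MAP2 without replicate 1. With only the NANOG and control libraries in the fit 10 genes passed, and NANOG, ZFP42, HHLA1, DPPA2, NLRP7, FGF4, MAP2, ZIC2 and PKM were not among them.

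In the MIR302 line the tagged transcript MIR302CHG was at 55.3 and 62.3 CPM against 87.7 and 64.2 in the control, a log2 change of -0.37 (SE 0.192, adjusted p = 0.729). MIR302CHG (ENSG00000249532), the host gene of the miR-302 cluster of pluripotent cells, lies on chromosome 4 from 112646476 to 112650051 on the minus strand, inside LARP7 on the plus strand (112637077 to 112657696), and the miR-302 precursors lie within it. Their reads cannot be separated here. Genes higher in the line were SLC30A8, a zinc transporter gene, at 7.79 and 7.61 CPM against 0.0769 and 0.114 (log2 change 6.33, SE 0.399, adjusted p = 0.00329), CCDC125 (5.72), the zinc finger gene ZNF880 (2.91) and PUS7L (2.08), which encodes a pseudouridine synthase-like protein. PUS7L was as high in the NANOG line (41.8 and 42.8 CPM) and higher in the ACTB intron 1 line. CCDC125 was at 0 in both day 0 libraries of the differentiation, cells of the same tag counted in another table. In all, 6 genes passed, all higher, against 2094 at an unadjusted p under 0.05 and 227 with DESeq2 (201 higher, 26 lower). No member of any list passed over all genes, although camera placed naive pluripotency (adjusted p = 4.14e-05), ATF4 (4.36e-09), Nodal (0.00462) and interferon genes (0.0104) high and glycolysis (4.42e-06) and heat shock genes (0.000122) low; with an estimated correlation the adjusted p-values were 0.228, 0.257, 0.33, 0.228, 0.228 and 0.228. Adjusted over the list alone, 4 naive pluripotency, 2 ATF4 and 2 interferon genes rose. The count was 2 and 3 without MIR302 replicate 1 and 2, 101 (86 higher, 15 lower) and 737 (328 higher, 409 lower) without control replicate 1 and 2, and 0 with only the compared libraries in the fit; CCDC125 and PUS7L lost their calls without either MIR302 replicate.

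With the reporter in intron 1 of ACTB, the beta-actin gene (chromosome 7, 5526409 to 5563902, minus strand), ACTB was at 1790 and 1690 CPM against 1430 and 2150 (adjusted p = 0.931). CHCHD2, which encodes a mitochondrial intermembrane space protein, was at 0.136 and 0.0568 CPM against 22.5 and 38.2 in the control (log2 change -8.29, SE 0.431, adjusted p = 0.000664). PUS7L rose by 3.02 (SE 0.167) to 80.3 and 82.7 CPM, ZNF880 rose by 2.09, the synaptotagmin gene SYT3 fell by 3.09 and the membrane protein gene LY6E fell from 31.2 and 54.8 CPM to 7.1 and 6.15. These were all 5 genes past the threshold, against 3051 at an unadjusted p under 0.05 and 371 with DESeq2. No list member passed over all genes, although camera placed the Nodal (adjusted p = 0.00982), naive pluripotency (0.026), cell cycle (0.026) and interferon lists (0.0297) high; with an estimated correlation the adjusted p-values were 0.65, 0.65, 0.65 and 0.62. The count was 2 without either ACTB intron 1 replicate, 20 and 7019 without control replicate 1 and 2, 8 with DESeq2 size factors and 0 with only the compared libraries in the fit. ZNF880, SYT3 and LY6E lost their calls without either ACTB intron 1 replicate. Every comparison with the reporter control rests on 2 libraries that stand apart: they correlate at 0.965 with each other, while control replicate 2 correlates at 0.985 with both ACTB intron 1 libraries, and their chi-square per degree of freedom is 216.

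The lines labelled ACTB polyA and SOX2 polyA were compared with the same reporter control across tables. ACTB was higher in both: 5680 and 4840 CPM in the ACTB polyA line and 4560 and 4740 in the SOX2 polyA line, against 1270 and 1790 (log2 changes 1.78 with SE 0.199, adjusted p = 0.000418, and 1.60 with SE 0.198, adjusted p = 0.00101). SOX2 (chromosome 3, 181711925 to 181714436, plus strand) was at 328 and 328 CPM in the SOX2 polyA line against 273 and 233 (adjusted p = 0.17). MIR302CHG rose by 2.95 in the ACTB polyA line and by 1.80 in the SOX2 polyA line, and LARP7, which overlaps it, by 2.52 and 1.47. The sizes of the ACTB and MIR302CHG increases depend on the control, as values scaled by factors from all genes of each table show. ACTB was at 3270 and 2990 CPM in wild-type DMSO cells, counted in another table. It was at 5110 and 4500 in ACTB polyA, 4280 and 4420 in SOX2 polyA and 1430 and 2140 in the reporter control. MIR302CHG was at 141 and 158 in wild type and 87.8 and 63.8 in the control. In ACTB polyA it was at 483 and 442, and in SOX2 polyA at 203 and 224. For ACTB and MIR302CHG, wild-type cells stood above the control and the polyA lines above wild type. The kinase gene CAMK2B rose by 6.67 and 7.16, and the thymidylate synthase gene TYMS by 1.59 and 0.74. In the SOX2 polyA line the pluripotency factor gene POU5F1 changed by -1.52, the surface marker gene CD24 by 1.18 and the neuronal tubulin gene TUBB3 by 1.65. Of 25 core pluripotency genes, 7 rose and 4 fell in the ACTB polyA line (9 and 4 over the list alone; camera adjusted p = 0.536) and 5 rose and 3 fell in the SOX2 polyA line (8 and 3; adjusted p = 0.0483, and adjusted p = 0.836 with an estimated correlation).

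Several abundant genes stood at 0 in the polyA lines. LDHA, the lactate dehydrogenase A gene, was at least 7570-fold lower in the ACTB polyA line and at least 9640-fold lower in the SOX2 polyA line. The 14-3-3 epsilon gene YWHAE was at least 8140-fold and 10400-fold lower, and the tubulin gene TUBB at least 18100-fold lower in the ACTB polyA line. LDHA and YWHAE held 0 counts in wild-type cells treated with DMSO and 0 at day 0 of the differentiation; TUBB held 3 and 1. In all, 323 genes at 10 CPM or more in the control held at most 3 counts in the polyA lines, and 13 of these had more than 3 counts in the wild-type DMSO libraries.

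Past the threshold were 7961 of 22931 genes in the ACTB polyA line (3746 higher, 4215 lower) and 3287 in the SOX2 polyA line (1982 higher, 1305 lower). Line and table cannot be told apart: with DMSO-treated wild-type cells as the control 12796 and 9186 genes passed, 5250 and 892 of them shared in direction with the counts above, and the changes of CAMK2B in the ACTB polyA line and of POU5F1 and TYMS in the SOX2 polyA line reversed to -0.46, 1.01 and -0.17. Mitochondrial genes took 4.65 to 5.39% of counts in the polyA lines and 1.53 to 2.09% in the control. The counts were 3528 and 5124 without ACTB polyA replicate 1 and 2, 1720 and 1723 without SOX2 polyA replicate 1 and 2, and 13763 and 11485 for the respective lines without control replicate 2; TYMS lost its call in the SOX2 polyA line without either of its replicates. Neither split was stable. In the SOX2 polyA line lower genes outnumbered higher ones without its replicate 1 (790 higher, 930 lower) and 2 (797, 926), without control replicate 2 (5228, 6257), with no filter on low counts (2572, 2754), with only whole control values (398, 508) and with the wild-type control (4463, 4723). The other settings kept more higher genes, most so without the genes empty in all whole-number human tables (1861 higher, 735 lower). In the ACTB polyA line higher genes led without its replicate 1 (1926, 1602) and without those empty genes (3700, 3621), and lower genes in the other settings.

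Within their own table, the polyA lines differed at MIR302CHG, at 504 and 439 CPM in the ACTB polyA line against 199 and 221 in the SOX2 polyA line (log2 change 1.17, SE 0.117, adjusted p = 0.00163), and at LARP7 (1.07). ACTB (0.19, adjusted p = 0.217) and SOX2 (0.05, adjusted p = 0.728) did not pass. Of 18 glycolysis genes, 11 rose and 1 fell, among them the kinase gene PDK1 (0.93), the triosephosphate isomerase gene TPI1 (0.78) and the hexokinase gene HK2 (-0.67), with adjusted p = 0.00576 for the list and adjusted p = 0.604 with an estimated correlation. Of 16 ATF4 response genes 9 rose and 2 fell (adjusted p = 0.0647), with the cystine transporter gene SLC7A11 at -1.43. The immediate early gene EGR1 was at 1.39 and 1.68 CPM against 24.2 and 16.8 (log2 change -3.69), the interferon-stimulated gene ISG15 changed by 1.38, and the endoderm factor gene FOXA2 by -2.45. CHCHD2 was at 0 in the ACTB polyA line and at 47.5 and 48.7 CPM in the SOX2 polyA line, at least 777-fold lower. The zinc finger genes ZFP41 and ZNF333 were at 0 in the ACTB polyA line, at least 58.5-fold and 48.2-fold lower, and ZNF680 was higher there by a ratio of 333 (interval 59.3 to 13200). In all 7697 of 20786 genes passed, 3845 higher and 3852 lower. The count was 2856 (1110 higher, 1746 lower) and 3254 (1263, 1991) without SOX2 polyA replicate 1 and 2, and 11828 (5790, 6038) and 12143 (5827, 6316) without ACTB polyA replicate 1 and 2; PDK1 and HK2 lost their calls without SOX2 polyA replicate 1.

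**Figure D1:**
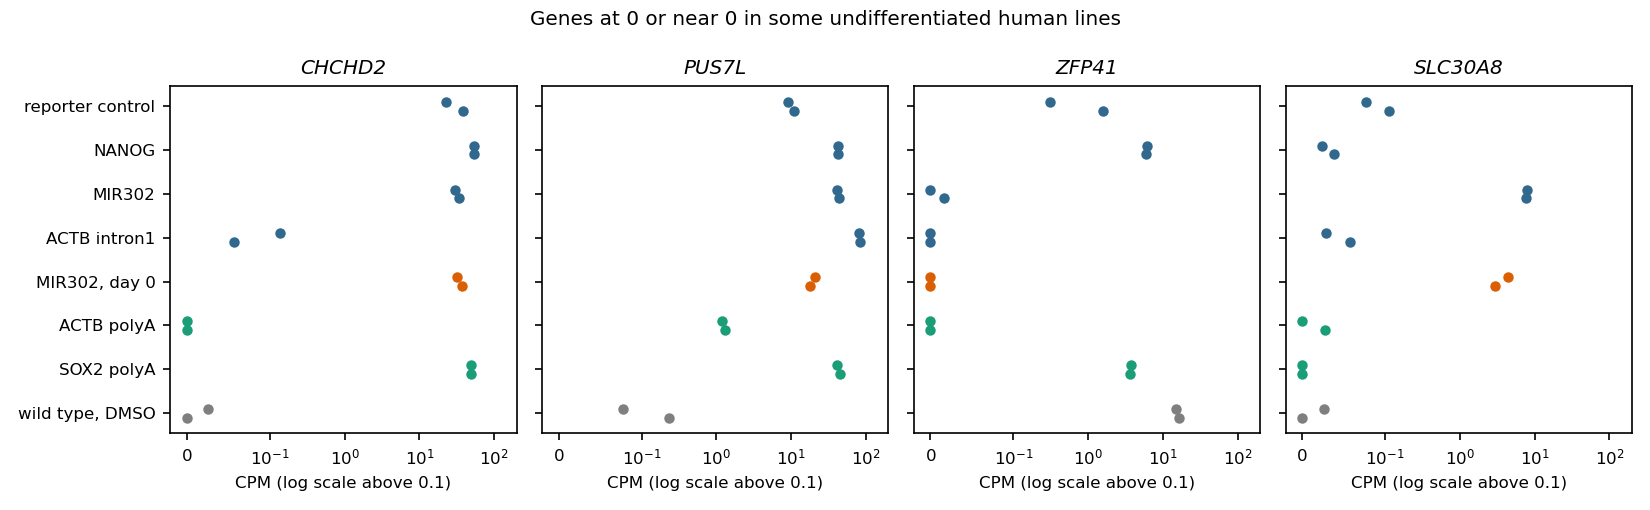
CPM (log scale above 0.1) of CHCHD2, PUS7L, ZFP41 and SLC30A8 in the undifferentiated human lines, each dot a library, with 2 per line; genes were chosen after their values were seen, and lines come from separately normalized tables. CHCHD2 lies near 0 in the ACTB intron 1, ACTB polyA and wild-type cells and at 22.5 CPM or more in the others, whereas ZFP41 is highest in the wild type at 14.9 and 16.3 CPM.

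In the mouse Lncenc1 line 14691 of 22696 genes passed against the mouse reporter control, 7402 higher and 7289 lower, of which 2969 were at least 2-fold higher and 1364 at least 2-fold lower. The replicates of this table lay close together. ENSMUSG00000024803 was at 6.36 and 6.17 CPM against 0 in both control libraries, at least 453-fold higher, and ENSMUSG00000051397 rose by 8.57 (SE 0.227, adjusted p = 1.59e-13). ENSMUSG00000030310 was at 1.87 and 1.44 CPM against 28 and 29.6 (log2 change -4.11, SE 0.0871, adjusted p = 1.47e-14), and ENSMUSG00000026443 changed by -4.09. Chromosome 6 held 215 genes at least 2-fold higher against 145 expected from its number of tested genes, and chromosome 13 held 90 at least 2-fold lower against 59.3, both looked at after the counts were seen and given without p-values, since neighbouring genes need not be independent. The tagged gene itself is not reported, since the identifiers were not paired with names. Leaving out each library in turn gave 12651 to 14502 genes.

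The differentiation asks how RNA from the MIR302 locus and the rest of the transcriptome change as MIR302-tagged cells leave pluripotency. Over days 0, 5, 12 and 20, 15273 of 21715 genes changed, which is 70.3%. MIR302CHG was still at 156 and 130 CPM at day 5 against 175 and 147 at day 0 (log2 change -0.17, SE 0.188, adjusted p = 0.51), and then stood at 8.41 and 9.63 at day 12 (-4.15, SE 0.22, adjusted p = 1.22e-06) and at 9.11 and 6.7 at day 20 (-4.34, SE 0.224, adjusted p = 1.03e-06). LARP7, on the other strand, changed by -0.23 (adjusted p = 0.282), -3.38 and -3.20 on the same days. NANOG had changed by -5.42 at day 5 and SOX2 by -4.94, and at day 12 NANOG was at 0, at least 594-fold lower.

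At day 5 genes of the primitive streak, of the endoderm and of the cardiac transcription factor list were high. The endoderm factor gene SOX17 stood at 383 and 410 CPM, at least 3650-fold higher than at day 0, the mesendoderm factor gene EOMES rose by 9.91 (SE 0.357), and the cardiac and endoderm factor genes GATA6 and GATA4 were at least 780-fold higher and higher by a ratio of 1240 (interval 222 to 48900). The cardiac repressor gene ANKRD1 was at 785 and 705 CPM, at least 6860-fold higher. The atrial myosin light chain gene MYL7 rose by 7.05 and the troponin gene TNNC1 by 5.54. ESRG, a noncoding RNA of pluripotent cells, fell by 8.21 and UTF1 by 6.90. Of the cholesterol synthesis genes, INSIG1 fell by 2.90 and HMGCS1 by 2.48.

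Of 24 core pluripotency genes 18 fell and 1 rose at day 5 (adjusted p = 9.34e-12, and adjusted p = 0.0411 with an estimated correlation). Of 14 primitive streak genes 11 rose (5.58e-06; adjusted p = 0.0341 with an estimated correlation), and of 17 cardiac transcription factors 11 rose (2.14e-05; adjusted p = 0.0411 with an estimated correlation). Of 18 sarcomere genes 9 rose and 2 fell (9 and 3 over the list alone; adjusted p = 0.0045, and adjusted p = 0.369 with an estimated correlation). Of 18 endoderm and hepatocyte genes 10 rose and 1 fell (0.00854; adjusted p = 0.687 with an estimated correlation). Of 20 cholesterol genes 19 fell (8.8e-10; adjusted p = 0.208 with an estimated correlation). Of 22 cell cycle genes 10 fell and 1 rose (12 and 1 over the list alone; adjusted p = 0.00051, and adjusted p = 0.147 with an estimated correlation). Of 17 interferon response genes 9 fell (10 over the list alone; adjusted p = 0.00869, and adjusted p = 0.317 with an estimated correlation). Of 18 glycolysis genes 9 fell and 3 rose, or 10 and 4 over the list alone (adjusted p = 0.0101, and adjusted p = 0.369 with an estimated correlation). In all 8064 genes passed, 3786 higher and 4278 lower. The count was 4486 and 4807 without day 0 replicate 1 and 2; it was 4594 (2670 higher, 1924 lower) and 4584 (2668, 1916) without day 5 replicate 1 and 2, and 13569 (6933, 6636) with only these libraries in the fit, where higher genes led.

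By day 12 all 18 endoderm and hepatocyte genes were higher (adjusted p = 9.39e-05, and adjusted p = 0.396 with an estimated correlation), with the fibrinogen genes FGA and FGB at least 12300-fold and 13700-fold higher and the transthyretin gene TTR at 4470 and 9330 CPM. Of 17 cardiac transcription factors 14 rose (15 over the list alone; adjusted p = 1.82e-05, and adjusted p = 0.0448 with an estimated correlation), among them GATA6, at least 1210-fold higher, and HAND1, at 609 and 87.7 CPM. Of 18 sarcomere genes 12 rose and 1 fell (14 and 1 over the list alone; adjusted p = 0.00139, and adjusted p = 0.283 with an estimated correlation), with MYL3, a myosin light chain gene, up by 6.99. Of 16 genes of fibroblasts, smooth muscle and epicardium 14 rose (15 over the list alone; adjusted p = 0.000683, and adjusted p = 0.283 with an estimated correlation); the collagen gene COL3A1 was at 1810 and 238 CPM and the proteoglycan gene LUM at 302 and 53. All 22 cell cycle genes fell (5.42e-11; adjusted p = 0.0364 with an estimated correlation), the replication genes MCM5 by 3.43 and PCNA by 3.28, while the antiproliferative gene BTG2 rose by 7.48; of the 18 p53 targets, which include it, 6 rose and 4 fell (adjusted p = 0.878). Of 24 core pluripotency genes 22 fell (23 over the list alone; adjusted p = 3.79e-14, and adjusted p = 0.0364 with an estimated correlation). Of 20 cholesterol genes 9 fell and 1 rose (8 and 1 over the list alone; adjusted p = 0.0271, and adjusted p = 0.514 with an estimated correlation), of 15 neuroectoderm genes 9 fell and 1 rose (9 and 2 over the list alone; adjusted p = 0.00359, and adjusted p = 0.107 with an estimated correlation), and of 17 interferon response genes 9 fell and 2 rose (0.0169; adjusted p = 0.283 with an estimated correlation). In all 11716 genes passed, 6079 higher and 5637 lower. The day 12 libraries were unlike each other, with a correlation of log values across genes of 0.941.

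At day 20, 15 of 18 sarcomere genes were higher and 1 lower than at day 0 (adjusted p = 6.96e-05, and adjusted p = 0.193 with an estimated correlation), with MYL7 up by 7.12 and MYL4 at 53.1 and 70.8 CPM. Such counts do not show levels, so further genes were picked after their values were seen, scaled by factors from all genes. TNNT2 was at 108 and 117 CPM. The cardiac myosin gene MYH6 was at 5.45 and 0.27 CPM, against 0.296 and 0.533 at day 0. AFP, the alpha-fetoprotein gene, was at 8750 and 1110 CPM. Of 17 cardiac transcription factors 16 rose (1.43e-06; adjusted p = 0.028 with an estimated correlation), HAND2 at least 1760-fold. Of 16 fibroblast, smooth muscle and epicardium genes 15 rose (1.75e-06; adjusted p = 0.193 with an estimated correlation), with COL3A1 at 4590 and 19100 CPM, LUM at least 25000-fold and DCN, another matrix proteoglycan gene, at least 10700-fold higher. All 18 endoderm and hepatocyte genes were higher (0.000544; adjusted p = 0.451 with an estimated correlation), but TTR was at 3420 CPM in replicate 1 and 119 in replicate 2, and FGB at 1400 and 135. All 24 core pluripotency genes were lower (1.21e-14; adjusted p = 0.028 with an estimated correlation), ESRG at least 7690-fold and ZSCAN10 at least 1370-fold. All 20 cholesterol genes fell (5.41e-08; adjusted p = 0.193 with an estimated correlation), HMGCS1 by 2.77, as did 21 of 22 cell cycle genes (1.41e-08; adjusted p = 0.028 with an estimated correlation) and 12 of 18 glycolysis genes, of which 1 rose (0.00125; adjusted p = 0.213 with an estimated correlation). Of 15 genes of cardiac calcium handling and channels more fell than rose: 2 rose and 4 fell at day 5 (adjusted p = 0.497), and 2 rose and 6 fell at day 12 (0.102) and at day 20 (3 and 7 over the list alone; 0.153). TRDN, which encodes the calcium release protein triadin, was at 0, at least 117-fold lower. Of 13 heat shock and immediate early genes 7 rose and 2 fell (8 and 2 over the list alone; adjusted p = 0.021, and adjusted p = 0.257 with an estimated correlation), among them ATF3 (3.72) and DUSP1 (3.44). Of 15 neuroectoderm genes 9 fell and 2 rose (adjusted p = 0.03, and adjusted p = 0.193 with an estimated correlation). In all 12184 genes passed, 6203 higher and 5981 lower. This lead of higher genes was not stable, since lower genes led when either day 0 replicate was left out.

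**Figure D2:**
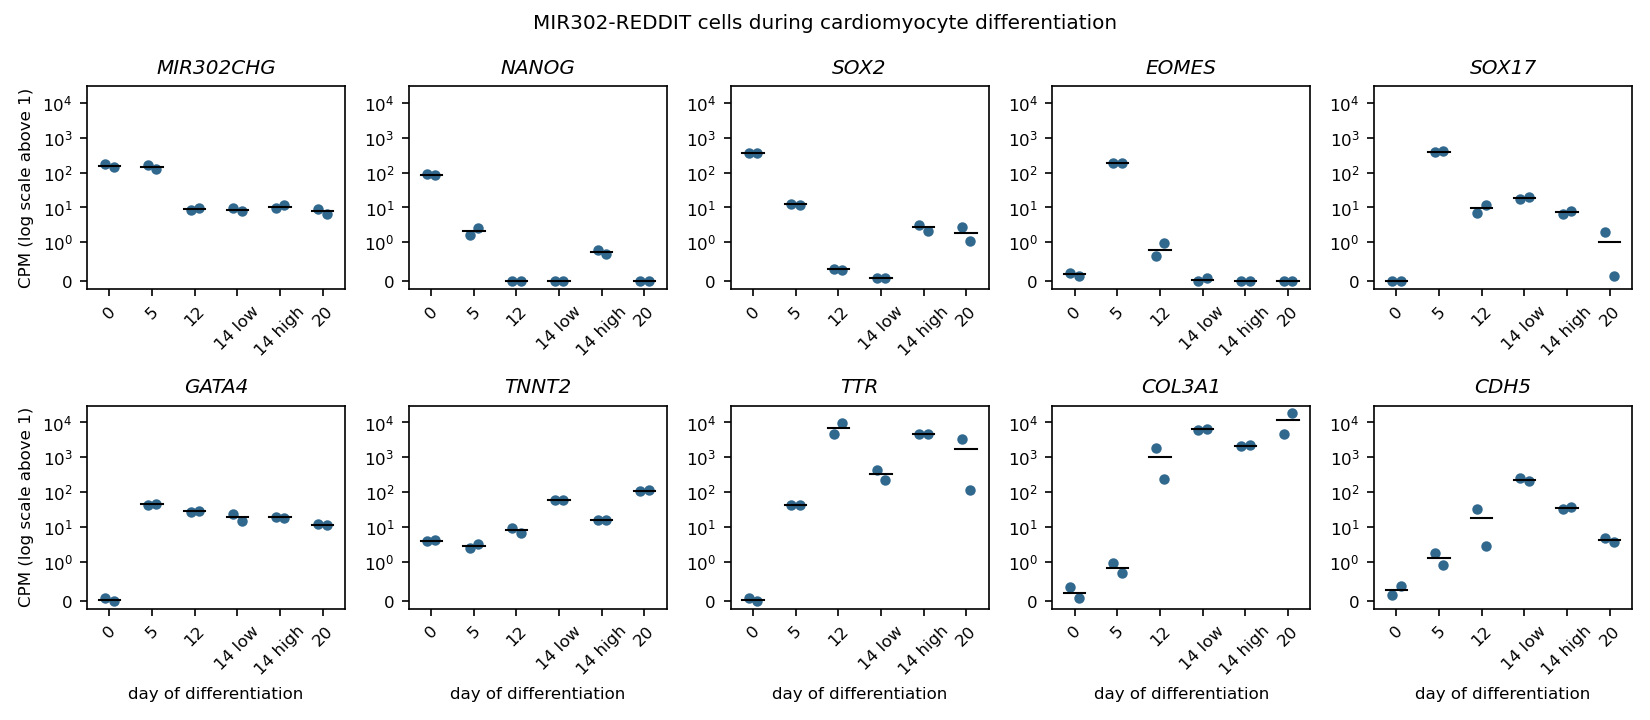
CPM (log scale above 1) of 10 genes in MIR302-tagged cells by day of differentiation; dots are the 2 libraries per group and bars their mean, and genes outside the naming rule were chosen after their values were seen. MIR302CHG holds its day 0 level at day 5 and lies near 10 CPM from day 12 on, while the day 20 libraries part at TTR (3390 and 117 CPM) and COL3A1 (4560 and 18800 CPM).

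At day 14 the labels name a high and a low group without saying what was high or low. MIR302CHG was at 9.25 and 11.3 CPM in high and at 9.52 and 7.77 in low (log2 change 0.25, SE 0.209, adjusted p = 0.4). Genes of undifferentiated cells were detected in the high group: TDGF1, a Nodal co-receptor gene, was at 7.69 and 6.85 CPM against 0 and ESRG at 6.48 and 6.35 against 0, at least 55.9-fold and 49.3-fold higher, and NANOG at 0.778 and 0.695 against 0, at least 5.66-fold. SOX2 was higher by a ratio of 30.9 (interval 8.17 to 261). Scaled by factors from all genes, SOX2 was at 3.25 and 2.12 CPM in high and at 2.73 and 1.08 at day 20. NANOG was at 0 in those day 20 libraries, so SOX2 counts alone do not mark undifferentiated cells here. Endothelial genes were lower in high, such as TEK, an angiopoietin receptor gene, by 3.19 and the cadherin gene CDH5 by 2.69. The replication genes RRM2 and PCNA fell by 2.36 and 2.19, and the cholesterol enzyme genes MSMO1 and DHCR7 rose by 2.96 and 1.92. The stress cytokine gene GDF15 was at 41.3 and 42.6 CPM against 1.39 and 2.21 (4.53).

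Of 24 core pluripotency genes 14 rose and 1 fell in high (16 and 1 over the list alone; adjusted p = 4.84e-06, and adjusted p = 0.113 with an estimated correlation). Of 14 endothelial genes 11 fell (12 over the list alone; adjusted p = 1.19e-07, and adjusted p = 0.373 with an estimated correlation), as did 6 of 16 genes of fibroblasts, smooth muscle and epicardium (8 over the list alone; adjusted p = 0.000849, and adjusted p = 0.406 with an estimated correlation). Of 18 endoderm and hepatocyte genes 9 rose and 2 fell (9 and 3 over the list alone; adjusted p = 0.00793, and adjusted p = 0.688 with an estimated correlation), with TTR at 4540 and 4700 CPM against 424 and 226. Of 20 cholesterol genes 14 rose (15 over the list alone; adjusted p = 4.72e-08, and adjusted p = 0.373 with an estimated correlation), and of 22 cell cycle genes 14 fell (15 over the list alone; adjusted p = 3.13e-09, and adjusted p = 0.0624 with an estimated correlation). Of 13 heat shock genes 6 fell (0.0129; adjusted p = 0.376 with an estimated correlation), the small heat shock protein gene HSPB1 by 2.09. Of 18 sarcomere genes 5 rose and 4 fell (adjusted p = 0.439). In all 6059 genes passed, 3095 higher and 2964 lower. The count was 1827 (1173 higher, 654 lower) and 1785 (1168, 617) without high replicate 1 and 2, and 3318 (1865, 1453) and 2265 (1120, 1145) without low replicate 1 and 2. CDH5 and TTR lost their calls when any of the 4 libraries was left out, TEK without either high replicate or low replicate 1, and GDF15 without either low replicate.

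UNC0638 inhibits the histone H3 lysine 9 methyltransferases G9a and GLP, and its comparison with DMSO asks which genes depend on them in mouse embryonic stem cells. At 10 µM for 48 h, 441 of 19675 genes rose and 6 fell, and after 7 days 584 rose and 104 fell. Most of the raised genes were near silence in DMSO: their median in the 48 h DMSO libraries was 0.287 CPM, against 9.15 for all tested genes, and 28 of them were at 0. The selection favours such genes. A gene silent in DMSO passes the filter only if another group reads it, and only 13 of 100 simulated 2-fold changes were recovered at 48 h. The low median therefore does not show that genes low in DMSO respond more. At 48 h 378 rose at least 4-fold. ENSMUSG00000082164 was at 4.13 and 3.93 CPM against 0, at least 59.9-fold higher, and ENSMUSG00000110761 at least 42.6-fold higher, while ENSMUSG00000051455 was at 10.9 and 10.3 CPM against 28.5 and 34.4 (log2 change -1.56, SE 0.258, adjusted p = 0.0325) and ENSMUSG00000109032 changed by -1.18. At 7 days ENSMUSG00000051827 and ENSMUSG00000058328 were at least 68.4-fold and 66.7-fold higher, and ENSMUSG00000063672 and ENSMUSG00000024619 changed by -2.38 and -2.37.

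Of the 441 genes raised at 48 h, 312 were also raised at 7 days, which is 70.7%, where independent lists of these sizes would share 13.1; the DMSO libraries of both times are separate. In direction, 437 of them (99.1%) were higher at 7 days, with a median log2 change of 3.43 beside 4.31 at 48 h, medians of fitted values that include genes at 0 in DMSO. A test of the difference between the times called 1 gene with edgeR, against 1294 at an unadjusted p under 0.05 and 69 with DESeq2. At 48 h chromosomes 12 and 13 held 38 and 35 raised genes against 16.9 and 18.6 expected, and at 7 days chromosomes 1 and 12 held 57 and 39 against 34.1 and 22.4 and the X chromosome 43, also above its expected number; these were looked at after the counts were seen and are given without p-values, since raised genes lie side by side.

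The UNC0638 counts rest on few libraries. At 48 h the count of 447 was 75 and 78 without DMSO replicate 1 and 2, 114 without either UNC0638 replicate and 6316 with only the 48 h libraries in the fit, where the directions evened out to 3243 higher and 3073 lower. At 7 days the count of 688 was 8580 (5003 higher, 3577 lower) and 1380 (983 higher, 397 lower) without DMSO replicate 1 and 2, 124 and 120 without UNC0638 replicate 1 and 2, and, with only the 7-day libraries in the fit, 0 without a replicate block and 859 with the block (676 higher, 183 lower, 568 shared in direction with the 688). No named gene kept its call in the fit without the block or without a UNC0638 replicate, and all 4 kept it with the 7-day libraries alone and the block. At 48 h no named gene but ENSMUSG00000110761 kept its call when a library was left out, and that gene lost it without UNC0638 replicate 2. The difference between the times gave 7274 and 9 genes without the 7-day DMSO replicate 1 and 2 and 0 without any of the other libraries.

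**Figure D3:**
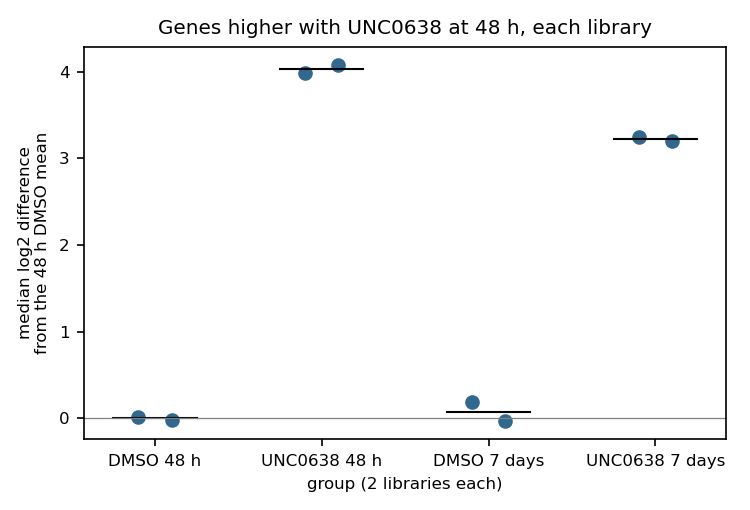
Median log2 difference from the mean of the 48 h DMSO libraries over the 441 genes raised by UNC0638 at 48 h, each dot a library, with 2 per group and bars at the mean; the 48 h groups chose these genes. The 7-day UNC0638 libraries lie at 3.25 and 3.20 and the 7-day DMSO libraries at 0.189 and -0.0323.

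RepSox inhibits the type I TGF-beta receptor ALK5, and wild-type human cells treated with 10 µM RepSox were compared with DMSO-treated cells to ask which genes depend on Nodal, activin and TGF-beta signalling. Nodal target genes fell: CER1, a secreted Nodal antagonist, was at 0 against 12.6 and 13.7 CPM, at least 220-fold lower; LEFTY1, another antagonist, fell from 7.91 and 8.8 CPM to 0.127 and 0.151 (log2 change -5.87, SE 0.287, adjusted p = 2.69e-12); and the inhibitory SMAD7 fell by 3.29 (SE 0.131, adjusted p = 9.48e-14). NANOG was at 34.9 and 29.5 CPM against 75.9 and 82.9 (-1.30, SE 0.0868, adjusted p = 5.41e-10). MIR302CHG was at 161 and 188 CPM against 140 and 158 (0.23, SE 0.0787, adjusted p = 0.0894), and SOX2 (adjusted p = 0.328) and ACTB (0.793) did not pass. The receptor gene KDR rose by 1.11, to 694 and 602 CPM.

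Of 20 Nodal pathway genes 12 fell and none rose (1 rose and 12 fell over the list alone; adjusted p = 2.49e-18, and adjusted p = 0.398 with an estimated correlation). Of 24 core pluripotency genes 7 rose and 3 fell (10 and 3 over the list alone; adjusted p = 0.0054, and adjusted p = 0.427 with an estimated correlation), PRDM14 by 0.63 and NANOG among the falling. Of 14 neuroectoderm genes 5 rose and 3 fell (6 and 3 over the list alone; adjusted p = 0.00582, and adjusted p = 0.427 with an estimated correlation), with SOX21 at 1.47, SOX3 at 1.02 and HESX1 at -1.01. Of 20 cholesterol genes 3 rose (4 over the list alone; adjusted p = 0.00582, and adjusted p = 0.859 with an estimated correlation). Of 7 primitive streak and mesendoderm genes 2 rose and 0 fell, or 3 and 1 over the list alone. That list ranked high (camera adjusted p = 0.0397, and adjusted p = 0.427 with an estimated correlation). Of 23 TGF-beta matrix genes 4 rose and 1 fell (adjusted p = 0.0748). None of 16 interferon response genes and none of 13 heat shock genes passed. Outside the lists the channel gene TRPC6 rose by 2.14 and the smooth muscle actin gene ACTG2 by 2.09, and LRRN2 fell by 3.41. In all 1551 of 21971 genes passed, 807 higher and 744 lower, of which 109 and 130 changed at least 2-fold. The count was 932 without RepSox replicate 1 and 415 with no filter on low counts; without RepSox replicate 1 or without DMSO replicate 2 MIR302CHG passed as higher.

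**Figure D4:**
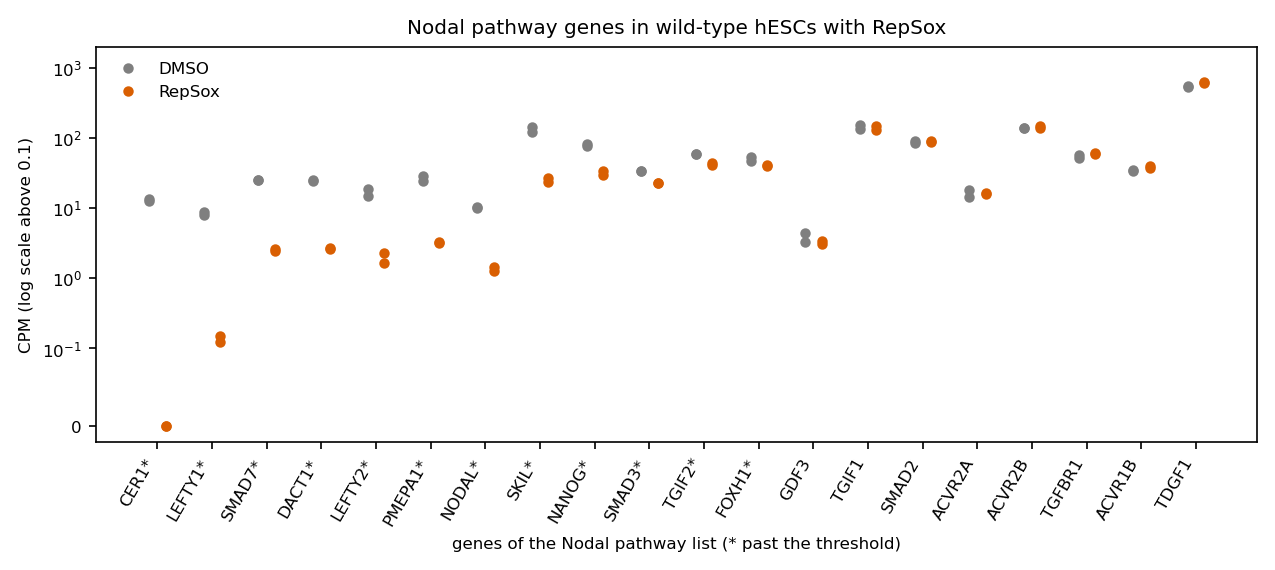
CPM (log scale above 0.1) of the 20 tested genes of the Nodal pathway list in wild-type human cells, with each of the 2 DMSO and 2 RepSox libraries as a dot and an asterisk on genes past the threshold. CER1 is at 0 in RepSox, NODAL lies at 1.46 and 1.28 CPM against 10.5 and 9.95, and TDGF1 at 627 and 606 against 533 and 556 did not pass.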

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

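The tests of silencing in the polyA lines, of spilled day 0 reads and of library depth were chosen after the results were seen.

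ENSMUSG00000000031, on chromosome 7 from 142575529 to 142578143 in mm10, differed between the times of UNC0638 treatment. It was at 188 and 197 CPM after 7 days against 10.2 and 11.4 in DMSO, and at 8.14 and 8.74 after 48 h against 7.45 and 7.11. The log2 change was 4.16 at 7 days (adjusted p = 0.000629) and 0.21 at 48 h (adjusted p = 0.721). The difference of 3.95 (SE 0.204, adjusted p = 0.00635) was the only one past the threshold in the test of the difference itself. That test called 7274 and 9 genes without the 7-day DMSO replicate 1 and 2, and 0 without any other library. No explanation was tested for this gene.

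The first pattern weighed is the 323 genes read at 10 CPM or more in the reporter control with at most 3 counts in the polyA lines, among them LDHA and YWHAE. Switching off in the polyA lines alone is not needed for most of them. Only 4.02% had more than 3 counts in wild-type DMSO cells, which carry no reporter. Those cells were also counted in whole numbers over the same gene set. If that counting empties a gene, its zeros cannot show whether the gene is on in either line. For the 13 genes read in wild-type cells, switching off in the polyA lines stays open. Reads lost to gene copies on sequences outside the main chromosomes could account for part of them: 61.6% have a gene of the same length there against 16.9% of other genes, a ratio of 3.65, which alone does not decide because lengths can match by chance. Matched together with a neighbour, the shares were 45.8% and 0.871%, a ratio of 52.6, which is consistent with whole stretches being present more than once in the reference, with reads that map to both left uncounted. The remaining genes stay unexplained. The control table holds fractional counts and the polyA table whole-number counts, and what this difference in counting does to these genes was not tested.

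The second pattern is the core pluripotency genes that were higher in the day 14 high group. Undifferentiated cells left among the high cells would raise other day 0 genes by one share. Of 9 such genes 8 (88.9%) lay within 3-fold of their median share of 0.582%. This is weak evidence for such a remnant, since the window is wide and set around the genes' own median. Day 0 reads carried into the high libraries alone would meet it too. Day 0 reads spilled evenly into all libraries would reach the low group too, but over the 24 core genes its median share was 8.27% of that in the high group, and TDGF1 and ESRG were at 0 there. The levels of some core genes are too high for that remnant alone: their median was 1.72%, and PODXL (47.6% in high and 8.18% in low), CD24 (41.7 and 9.4%), SALL4 (32.9 and 17.5%), LIN28A (27.4 and 12.3%) and GDF3 (14.8 and 2.61%) lay far above that share, in part in both groups. Some core genes had the larger share in low, among them LIN28B (39.4% in high and 58.5% in low) and TERF1 (4.19 and 6.65%). Another meaning of high and low stays open, since the labels do not give it.

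The third pattern is the 7-day DMSO libraries, which stand apart from each other: without replicate 1 the count at 7 days was 8580 and without replicate 2 it was 1380, against 688 with both. A UNC0638-treated library under the DMSO label does not hold, since the shift of replicate 2 over the genes raised at 48 h was -1% of that of the treated libraries. Lower depth does not hold either, with a total of 83.7% of replicate 1. Replicate 2 departs more from the 48 h DMSO libraries, with correlations of 0.913 and 0.908 against 0.975 and 0.969 for replicate 1. It had 23089 genes detected, against 26509 in replicate 1. The 7-day UNC0638 libraries had 27370 and 26494 at lower totals. Why fewer genes were detected in replicate 2 was not tested. The 7-day UNC0638 libraries with the same numbers deviate together with the DMSO ones (r = 0.636), so something shared by replicate number at 7 days stays open. No biological explanation was tested.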

How the results depend on the processing

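The settings that change the control or the genes for the polyA lines, the comparison of both polyA lines with each other and the 7-day libraries alone with the replicate block were chosen after the data were examined. Of 155 counts of genes under an alternative, 85 stayed within 1.5 times the reported count and 70 moved. Of 4144 values for named genes 3782 kept direction and side of the threshold, 294 lost the call, 60 gained it and 8 reversed; leaving out a replicate made 216 of the losses and 28 of the gains. Of 336 list results, with an estimated correlation or with fry, 241 kept their call, 82 lost it and 13 gained it. Values from fry are not printed beside the lists above. Some lists that lost their call with an estimated correlation kept it with fry. Examples are cholesterol genes at day 5 (fry adjusted p = 0.000175) and Nodal genes with RepSox (fry adjusted p = 0.047). Others lost it with fry too, as core pluripotency genes did in the NANOG line (fry adjusted p = 0.0827). Where a replicate was left out, the lone library is assumed to vary like the other groups. The RepSox comparison in GRO-seq, its difference from RNA and the mouse gene lists were planned and not run.

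With each replicate left out in turn the counts ranged from 33 to 2662 for NANOG, 2 to 737 for MIR302, 2 to 7019 for ACTB intron 1, 3528 to 13763 for ACTB polyA, 1720 to 11485 for SOX2 polyA, 2856 to 12143 for the polyA lines against each other, 12651 to 14502 for Lncenc1, 4486 to 4807 for day 5, 8573 to 11526 for day 12, 9160 to 11613 for day 20, 12534 to 16564 over the days, 1785 to 3318 for day 14, 75 to 114 for UNC0638 at 48 h, 120 to 8580 at 7 days, 0 to 7274 for their difference and 932 to 2058 for RepSox.

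With DESeq2 the counts were 1635 for NANOG, 227 for MIR302, 371 for ACTB intron 1, 749 and 1246 for UNC0638 at 48 h and 7 days and 69 for their difference. With no filter on low counts they were 2308 for NANOG, 728 for MIR302, 1759 for ACTB intron 1, 5326 for SOX2 polyA and 415 for RepSox. With only the compared groups in the fit they were 10 for NANOG, 0 for MIR302, 0 for ACTB intron 1, 13569 for day 5, and 6316 and 0 for UNC0638 at 48 h and 7 days. With DESeq2 size factors ACTB intron 1 gave 8. With only genes of whole control values ACTB polyA gave 2843 and SOX2 polyA 906. With wild-type DMSO cells as the control SOX2 polyA gave 9186 and ACTB polyA 12796; the log2 changes of ATF6-DT (-0.29) and CAMK2B (-0.46) in ACTB polyA and of ATF6-DT (-0.27), MIR302C (-1.25), MIR302D (-1.07), POU5F1 (1.01), TYMS (-0.17) and TMEM217B (-0.33) in SOX2 polyA reversed. The reported counts are those in the comparisons above, and the cause was not tested.

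The labels do not say that a replicate number marks a shared culture or day, and correlations of deviations between groups with the same numbers ran from -0.271 to 0.636. The highest, 0.636, is that of DMSO and UNC0638 at 7 days, whose replicates deviate together. With the replicate number as a block the counts were 245 for NANOG, 4 for MIR302, 3 for ACTB intron 1, 7611 for ACTB polyA, 3282 for SOX2 polyA, 7889 for the polyA lines against each other, 14757 for Lncenc1, 7476, 11234 and 11624 for days 5, 12 and 20, 14553 over the days, 5361 for day 14, 350 and 487 for UNC0638 at 48 h and 7 days, 1 for their difference and 2142 for RepSox; the 7-day libraries alone gave 859 with the block and 0 without it, so the block decides that count. The smallest library, in the differentiation, held 7.88 M counts, and what depth limits was not tested.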

Other observations

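The windows of neighbouring genes and the comparison of lines below were chosen after the results were seen, while the test of neighbouring genes raised by UNC0638 was written before its result.

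Genes raised by UNC0638 in mouse cells lie side by side. Of the 441 raised at 48 h, 37% were next to another raised gene among the tested genes, against a mean of 4.42% and at most 9.3% over 1000 random draws of as many genes; at 7 days the share was 32.7%, against a mean of 5.85% and at most 9.76%. On chromosome 12 from 87480108 to 87863967 (mm10), 10 of 10 neighbouring tested genes rose at 48 h and 8 of them at 7 days. Further runs at 48 h were 9 of 10 on chromosome 13 from 119827961 to 120241367, and 8 of 10 on chromosome 3 from 93669333 to 94158721 and on chromosome 5 from 93390602 to 94626848. At 7 days 9 of 10 rose on chromosome 1 from 87945119 to 88220002 and 8 of 10 on the X chromosome from 73033981 to 73292976. A hypothesis is that G9a and GLP silence domains that hold several genes. The share of 37% shows only that raised genes are neighbours. The draws came from all tested genes and were not matched for level in DMSO, where the raised genes were low. They do not show what share other genes of such low level would give. Reads shared among related neighbouring genes were not tested and could give the same pattern.

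A few genes separate the undifferentiated human lines. CHCHD2 was at 54 CPM in both NANOG libraries and at 48.3 and 49.4 in the SOX2 polyA line, but at 0.137 and 0.0571 in the ACTB intron 1 line, 0 in the ACTB polyA line, and 0.0258 and 0 in wild-type DMSO cells. PUS7L was at 80.8 and 83.1 CPM in the ACTB intron 1 line, 41.8 and 42.8 in the NANOG line and 9.19 and 10.9 in the reporter control. It was at 40.8 and 43.9 in the MIR302 line and at 20.8 and 17.9 in day 0 cells of the same tag. The polyA lines parted, with 41.6 and 44.4 for SOX2 polyA and 1.17 and 1.31 for ACTB polyA, and the wild type stood at 0.0774 and 0.234. SLC30A8 was read in the MIR302 line (7.78 and 7.57 CPM) and in day 0 cells of the same tag (4.43 and 2.93), and was at most 0.114 elsewhere. CCDC125, also called in the MIR302 line (3.54 and 4.19 CPM), was at 0 in both libraries of those day 0 cells. ZNF880 was highest in the MIR302 line (30.7 and 34.8 CPM), with 19.4 and 18 at day 0, 19.5 and 17.9 in the ACTB intron 1 line and 10.6 and 9.72 in the NANOG line.

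The libraries of day 12 and of day 20 were unlike their replicates. At day 20 AFP, the alpha-fetoprotein gene, was at 8750 CPM in replicate 1 and 1110 in replicate 2, while LUM was at 1010 and 4350. At day 12 AFP was at 10200 and 22000 CPM. The troponin gene TNNT2 was at 3.99 and 4.19 CPM at day 0 and at 2.51 and 3.29 at day 5. At day 12 it was at 9.5 and 6.9 CPM. It stood at 58.9 and 58.6 in day 14 low, 16.7 and 16.4 in day 14 high, and 108 and 117 at day 20.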
